A study of Hapsidospora chrysogena with 9 samples.

How the data were processed

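RNA was measured by sequencing in mycelium of Hapsidospora chrysogena, the filamentous fungus also called Acremonium chrysogenum and used to make cephalosporin C. The 9 libraries cover 3 strains at 48, 72 and 96 h of culture. The strains are the wild type, a strain in which the Myb transcription factor gene AcmybA was knocked out, and a strain that overexpresses it. Each strain and time has 1 library. Per the labels' protocols, mycelium was frozen in liquid nitrogen, RNA was extracted with Trizol, and polyadenylated RNA went into Illumina libraries.

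The submitters' processing notes name CASAVA, with no version, and HISAT2 2.0.5, with no role or order given. The genome build, annotation and counting tool are not given in the sources used here. The deposited table holds 1 value for each of 8899 genes in each library. Its header names only the libraries, so the unit was worked out from the deposited values, which are treated as FPKM, fragment numbers scaled by transcript length and library depth. They carry 6 significant digits, their sums run from 852915 to 1124540 per library, and low values step in multiples whose size depends on the gene and the library. All 9 value columns matched a library by name, and 0 columns were left unmatched.

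FPKM values are not counts, so the count tests planned for a table of counts were not run, and the test planned for normalised values was used. Genes at 1 FPKM or more in at least 3 libraries were tested, which left 8482; 124 genes were at 0 in every library. Values were taken as log2(FPKM + 1), with a pseudocount of 1. Every fold change below is on that scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 fitted strain plus time, both as factors with 3 levels, to all 9 libraries together, with an intensity trend in the prior variance. Two-sided moderated tests were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05 on the adjusted p. The fit leaves 4 residual degrees of freedom, to which the prior adds 3.26. The residual is the departure of the 9 libraries from additive strain and time effects. It is not a spread between repeated cultures, since the 3 libraries of a strain were sampled at different times. Libraries of different strains at the same time, each taken as its departure from its strain mean, correlated across genes at r from -0.0433 to 0.487, and time is in the fit as a factor. A call therefore means a strain difference shared by the 3 times, or a time difference shared by the 3 strains. Differences at a single time have no replicate check and no p-value. Whether time courses differed between strains was tested with a linear slope per 24 h for each strain, which leaves 3 residual degrees of freedom.

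The main test was tried on simulated data with 50 genes changed at each of several sizes among 8482. Noise was drawn independently for each gene, in a single draw per comparison. It used the moderated variances of the strain plus time fit, also for slopes. These need not match the residual variances of the data, so the shares are rough guides. A log2 change of 2 was called for 90% of genes in knockout against wild type, 92% in overexpression against wild type and 90% in overexpression against knockout. For 96 h against 48 h the share was 84%. A log2 change of 1 was called for 26%, 26%, 40% and 26% in the same order. For slopes, a log2 difference of 2 per 24 h was called for 78% of genes in knockout against wild type and 66% in overexpression against wild type. A slope difference of 1 per 24 h was called for 6% and 10%.

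Sequencing depth is not stated. It was estimated up to a common factor from what 1 read is worth at genes under 2 FPKM in every library, by a likelihood over whole-read ratios. A first scoring rule returned a wrong doubling on simulated reads and was replaced; the likelihood recovered all 30 simulated draws over 6 depth ratios. Relative to wild type at 96 h, depth came to 0.927 and 0.953 in wild type at 48 and 72 h. In the knockout it came to 2.39, 0.829 and 0.895 at 48, 72 and 96 h, and in overexpression to 1.77, 2.39 and 2.23. The knockout estimate at 48 h is loose, because the log-likelihood of 1.20 was lower by only 1.56. In the other libraries the next best depth was lower by 8.66 or more. Between 47.7% and 74.4% of the low values lay within 0.02 on the log2 scale of a whole-read ratio. The simulated reads all lay at such ratios, so their recovery need not carry over to these libraries. By these estimates the 3 overexpression libraries are the deeper ones next to wild type, and depth cannot be separated from that strain. Low genes are measured less precisely in the shallower libraries.

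Genes carry protein identifiers without names or descriptions, and no annotation was used here. The 28 gene lists fixed before the data were examined, among them cephalosporin biosynthesis, conidiation and stress response, matched 0 genes and gave no result. AcmybA was not picked out by name, so its level could not be used as a check of the strain labels. By the naming rule fixed beforehand for tables without gene names, at most 2 identifiers are named each way for each strain comparison and for 96 h against 48 h. They are the largest log2 fold changes among genes with an adjusted p under 0.05, a difference of the same sign at all 3 times or in all 3 strains, and a mean of at least 10 FPKM. Genes named outside this rule are marked as chosen after their values were seen.

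Some genes are listed at 0 in 1 or more libraries and at 10 FPKM or more wherever they are detected. An exact 0 in such a table can be a failed estimate, so no fold is given against libraries listed at 0. Comparisons of both mutants with the same 3 wild-type libraries share chance values, which were gauged by 100 simulations of unchanged strains. Alternatives covered the test, the normalisation, the filter, the pseudocount, the time term, the libraries in the fit, and each library or time left out. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.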

Results

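Transcript levels of 8899 genes were compared between 3 strains of the cephalosporin producer H. chrysogena, the wild type, an AcmybA knockout and an AcmybA overexpression strain. Mycelium was sampled at 48, 72 and 96 h, with 1 library per strain and time. Nothing says that any library was repeated from a separate culture, so p-values measure departure from additive strain and time effects in these 9 libraries. Summed FPKM ran from 852915 to 1124540 per library and median FPKM from 37.8 to 42.2. Genes listed at 0 numbered 503, 430 and 424 in wild type at 48, 72 and 96 h. They numbered 302, 477 and 430 in the knockout and 402, 311 and 331 in overexpression. Estimated depth relative to wild type at 96 h was 1.77 to 2.39 in the overexpression libraries and 0.829 to 2.39 in the knockout libraries.

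Strain accounted for 42.2% of the sum of squares of log2(FPKM + 1), time for 31.0%, and departure from additivity for 26.7%. These are raw sums of squares, so the shares of strain and time also hold residual spread and overstate both effects. The 72 and 96 h libraries of a strain were the closest pairs, with r across genes of 0.947 in wild type, 0.928 in the knockout and 0.961 in overexpression. Wild type at 48 h was nearest to the knockout at 48 h, with r = 0.902. Genes are not independent replicates, so these correlations describe the libraries only.

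**Figure D1:**
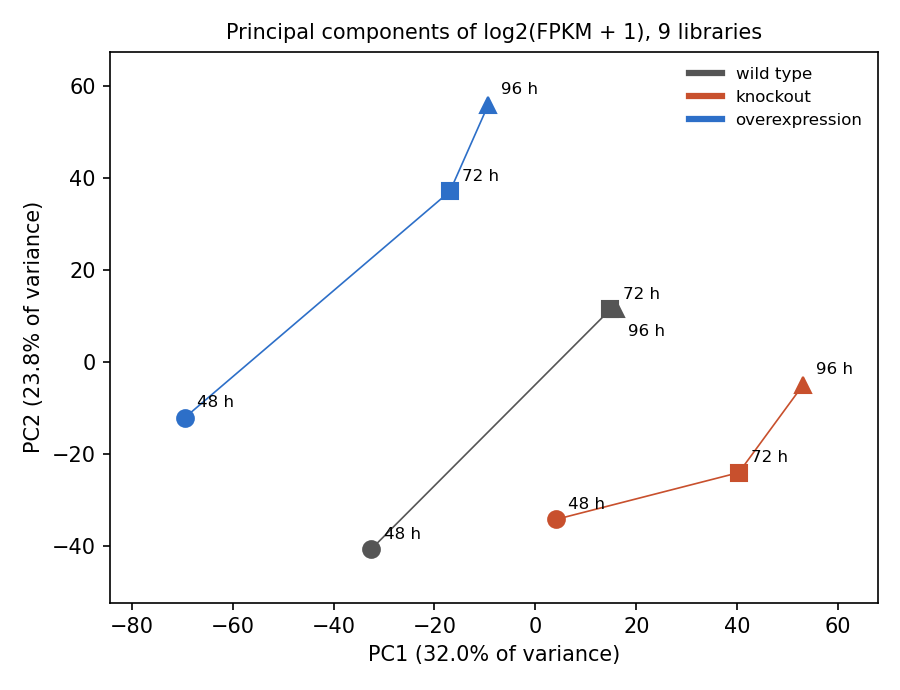
Principal components of log2(FPKM + 1) over the tested genes, with PC1 (32.0% of variance) on the horizontal and PC2 (23.8%) on the vertical axis. Each point is 1 library, coloured by strain and marked by time, with lines joining the times of a strain. In each strain the 48 h library lies at lower PC1 than those at 72 and 96 h, and the knockout libraries lie at higher PC1 than those of overexpression. Wild type overlaps both mutants along PC1 and along PC2 taken singly. Along the diagonal of the plane the strains lie in separate bands, with wild type between the mutants.

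The first comparison asks which transcripts changed when AcmybA was lost. In the knockout, 99 genes were higher and 80 lower than in wild type. The 99 higher genes had a median log2 fold change of 2.45, and their summed FPKM took 3.73%, 9.98% and 14.8% of the knockout libraries at 48, 72 and 96 h, against 0.292%, 1.62% and 1.74% in wild type. The 80 lower genes had a median log2 fold change of -1.81 and took 0.521%, 0.561% and 0.388% of the knockout libraries, against 1.89%, 1.87% and 1.57% in wild type. These groups were chosen on the same libraries, so their shares describe size and are not a separate test.

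KFH44385.1 was at 742, 2287 and 2335 FPKM in the knockout at 48, 72 and 96 h, and at 4.10, 89.6 and 45.3 FPKM in wild type. Its log2 fold change was 5.83 (SE 0.83, limma adjusted p = 0.020). KFH42174.1 rose to 54.9, 138 and 336 FPKM from 0.430, 10.9 and 2.0 in wild type, a log2 fold change of 5.21 (SE 0.59, limma adjusted p = 0.00985). Its call ended without all 48 h or all 96 h libraries (adjusted p = 0.0644 and 0.0650) and with no time term (0.0755), where that of KFH42220.1 below ended too (0.0619). Among the lower genes, KFH42220.1 was at 61.4, 34.0 and 13.9 FPKM in the knockout, against 964, 397 and 350 in wild type. Its log2 fold change was -4.00 (SE 0.28, limma adjusted p = 0.00369). KFH47843.1 was at 5.89, 3.01 and 2.77 FPKM against 168, 61.0 and 39.3, also a log2 fold change of -4.00 (SE 0.31, limma adjusted p = 0.00450). Both lower genes were also below wild type in overexpression, with log2 fold changes of -1.97 and -1.60 (limma adjusted p = 0.0188 and 0.0423). These overexpression calls ended without 1 library in 5 of 9 cases for KFH42220.1 (adjusted p from 0.0512 to 0.0947) and in 8 of 9 for KFH47843.1 (0.0581 to 0.179).

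All 179 genes differed in the same direction at all 3 times. A call nearly requires this, since differences that vary between times raise the residual, so it is no separate check. Of the 179, 175 had a log2 fold change of at least 1 in size. At an unadjusted p under 0.05 there were 1296 genes, where chance alone gives 424. Leaving out 1 library gave 30 to 235 genes, with 30 without wild type at 72 h, 51 at 96 h and 82 at 48 h. Without the knockout at 48, 72 or 96 h the counts were 74, 100 and 59, and without overexpression at 72 h 97. Of the 179 genes, 25 were called whichever library was left out. The call of KFH44385.1 ended without wild type at 72 or 96 h or any knockout library, with adjusted p from 0.0508 to 0.0828 and log2 fold changes from 5.69 to 6.65. It also ended without all 72 h or all 96 h libraries (0.0824 and 0.133) and with no time term (0.0569).

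The second comparison asks which transcripts changed when AcmybA was overexpressed. Lower genes prevailed, with 215 lower and 64 higher than in wild type. The 215 lower genes took 1.28%, 1.88% and 1.74% of the summed FPKM in overexpression at 48, 72 and 96 h. In wild type they took 14.5%, 8.20% and 6.70%, and in the knockout 7.50%, 7.93% and 6.46%. The 64 higher genes took 0.972% to 1.59% of the overexpression libraries and 0.312% to 0.345% of the wild-type libraries. Median log2 fold changes were -1.79 for the lower and 1.49 for the higher genes.

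KFH42067.1, the most abundant transcript of wild type at 48 h with 8.84% of its summed FPKM, was at 516, 157 and 254 FPKM in overexpression. In wild type it was at 93100, 18436 and 7115 FPKM and in the knockout at 34236, 14243 and 1212. Its log2 fold change against wild type was -6.39 (SE 0.79, limma adjusted p = 0.0132). KFH44846.1 was at 12.7, 17.0 and 10.6 FPKM in overexpression and 543, 702 and 446 in wild type, a log2 fold change of -5.29 (SE 0.33, limma adjusted p = 0.00239). KFH48583.1 was at 537, 500 and 386 FPKM in overexpression, 55.4, 19.1 and 26.7 in wild type and 3.36, 4.87 and 5.72 in the knockout. It was higher in overexpression by a log2 fold change of 3.90 (SE 0.37, limma adjusted p = 0.00777) and lower in the knockout by one of -2.50 (limma adjusted p = 0.0217). KFH43187.1 was at 10.1, 80.5 and 55.3 FPKM in overexpression and 2.18, 2.67 and 3.41 in wild type, a log2 fold change of 3.32 (SE 0.63, limma adjusted p = 0.0399).

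All 279 genes kept 1 direction at all 3 times, which a call nearly requires, and 264 had a log2 fold change of at least 1 in size. There were 1630 genes at an unadjusted p under 0.05, against 424 by chance. The count fell to 104, 14 and 47 without wild type at 48, 72 and 96 h. It was 19 and 83 without overexpression at 72 and 96 h and 181 without the knockout at 72 h, and 9 of the 279 genes were called whichever library was left out. A fit with 1 library fewer also has less power, and its part in these falls was not tested. KFH42067.1 missed the threshold without wild type at 72 or 96 h or overexpression at 72 h, with adjusted p from 0.0586 to 0.0888. It also missed it without all 48 h or all 72 h libraries (0.0559 and 0.168) and with no time term (0.0655). KFH48583.1 missed it against wild type without overexpression at 72 h, at 0.0553, and without all 72 h or all 96 h libraries, at 0.135 and 0.0653. Its call in the knockout ended in 5 of 9 cases, without wild type at 72 or 96 h or any knockout library (0.0508 to 0.0879). KFH43187.1 missed it in 11 of 25 alternatives, and without wild type at 48, 72 or 96 h its adjusted p was 0.0877, 0.164 and 0.163. Without the knockout at 96 h it was 0.0615, and without overexpression at 72 or 96 h 0.145 and 0.134. Without all 72 h or all 96 h libraries it was 0.218 and 0.240, with equal totals 0.0544, with no time term 0.0732 and with a pseudocount of 0.1 0.0744.

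**Figure D2:**
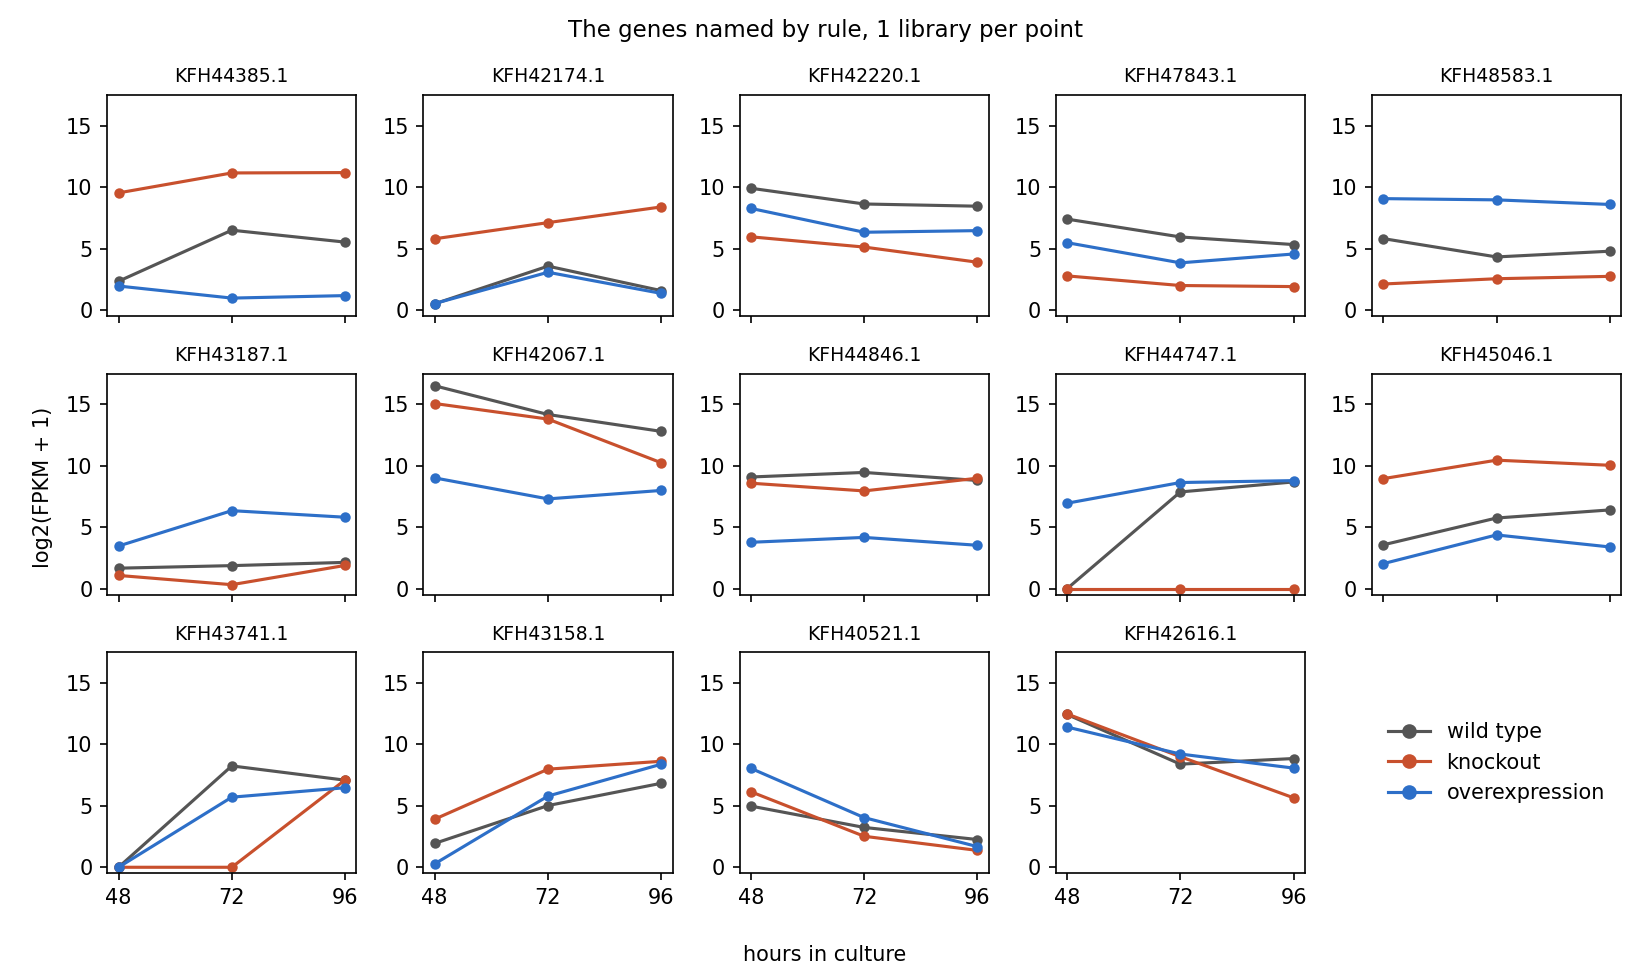
Levels of the named genes on a log2(FPKM + 1) axis against hours in culture, with 1 library per point and a line per strain. KFH44385.1 lies highest in the knockout at each time, KFH42067.1 lies lowest in overexpression, and KFH48583.1 is ordered knockout, wild type, overexpression from low to high.

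Overexpression and knockout differed from each other in more genes than either did from wild type, with 297 genes higher and 459 lower in overexpression. With equal FPKM totals these were 329 and 362, after median-of-ratios rescaling 296 and 484, and after quantile normalisation 352 and 475. The excess of lower genes thus stayed in each, but its size depends on the scaling and was small with equal totals. The 459 lower genes took 2.04%, 4.62% and 4.04% of the overexpression libraries at 48, 72 and 96 h, and 14.1%, 20.7% and 25.6% of the knockout libraries. The 297 higher genes took 4.91% to 7.72% in overexpression and 1.64% to 1.74% in the knockout. Wild type lay between the mutants at all 3 times for 146 of the 297 (49.2%) and 205 of the 459 (44.7%). A random order of strains at each time gives 3.70%, and all tested genes gave 9.13%. Neither is a baseline for genes chosen for a wide gap between the mutants, which often have wild type between them.

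KFH44385.1 differed most, at 2.89, 0.971 and 1.27 FPKM in overexpression, a log2 fold change of -9.25 against the knockout (SE 0.83, limma adjusted p = 0.00155). KFH45046.1 was at 3.11, 19.7 and 9.53 FPKM in overexpression, 10.9, 52.8 and 83.9 in wild type, and 495, 1403 and 1052 in the knockout. Its log2 fold change was -6.55 (SE 0.36, limma adjusted p = 0.000772). KFH48583.1 was higher in overexpression by a log2 fold change of 6.40 (SE 0.37, limma adjusted p = 0.000772). KFH44747.1 was listed at 0 in all 3 knockout libraries and in wild type at 48 h, at 233 and 411 FPKM in wild type at 72 and 96 h, and at 123, 397 and 442 FPKM in overexpression. It passed the test (limma adjusted p = 0.0202), but it is among the genes with gaps at 0, and no fold is given.

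Of the 756 genes, 644 had a log2 fold change of at least 1 in size, and 2031 had an unadjusted p under 0.05. The count was 386 and 379 without the knockout at 72 and 96 h, and 302 and 413 without overexpression at those times; 246 genes were called whichever library was left out. KFH44747.1 lost its call without the knockout at 72 or 96 h (adjusted p = 0.0857 and 0.0834). Without overexpression at 48, 72 or 96 h its adjusted p was 0.0637, 0.0752 and 0.0613. Without all 72 h or all 96 h libraries it was 0.157 and 0.0966, and with no time term 0.0561.

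Of the genes called against wild type in both mutants, 25 were lower in both, against 2.03 for independent lists of these sizes, and 1 was higher in both, against 0.747. The number lower in both was 15, 0 and 1 without wild type at 48, 72 and 96 h, 9, 10 and 7 without the knockout, and 21, 1 and 13 without overexpression. Genes called in opposite directions numbered 12. Of these, 9 were higher in the knockout and lower in overexpression, against 2.51, and 3 were lower in the knockout and higher in overexpression, against 0.604. Without wild type at 48, 72 or 96 h the opposite genes numbered 5, 0 and 1. Without the knockout at those times they numbered 5, 1 and 1, and without overexpression 27, 2 and 5. Unchanged strains simulated with shared control libraries gave a mean of 0.02 shared calls over all 4 classes. With no strain effect few genes can pass for either mutant, so this mean cannot gauge the overlap of lists as long as these. The 3 wild-type libraries cannot be split into sets of at least 2, so part of the excess in the same direction may come from these shared controls. Both comparisons also use the same residual variance for each gene. A gene with a small one passes more easily in both, in the same or opposite directions. The numbers for independent lists are therefore not a baseline, and neither excess can be read as a shared or opposed effect of the mutants.

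Across genes, the log2 fold changes of the mutants correlated at r = 0.212, below the mean of 0.501 from simulated unchanged strains (range 0.419 to 0.546). Their covariance was 0.103, above the simulated mean of 0.0671 (range 0.0525 to 0.0794), a difference of 0.0360. The same sign was seen for 59.3% of genes, against 66.6% in the simulations (range 65.4% to 67.9%). Strain differences widen the spread of both fold changes and can pull r and this share below the simulated values. Neither low value therefore shows the mutants to be less alike than unchanged strains. The covariance is not diluted in this way, but its simulated size depends on the noise put in. That noise was drawn independently for each gene from the moderated variances of the fit, which need not match the residual variances of the data. The difference of 0.0360 therefore cannot be read as an effect shared by the mutants.

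**Figure D3:**
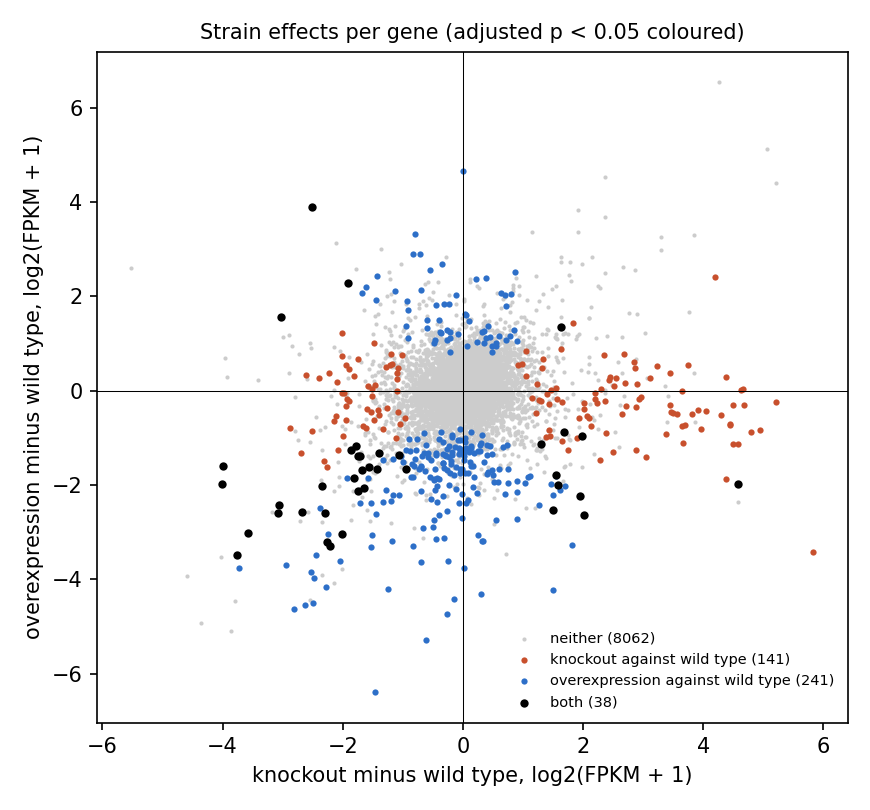
Difference from wild type in log2(FPKM + 1) for the knockout (horizontal) and overexpression (vertical), with 1 point per tested gene. Colours mark an adjusted p under 0.05 in the knockout, in overexpression or in both, and most genes called in both lie in the lower left, where 25 are lower in both mutants.

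Between 48 and 96 h, 508 genes rose and 525 fell in the 3 strains together, with median log2 fold changes of 1.46 and -1.07. Median-of-ratios rescaling gave 596 rising and 405 falling, and quantile normalisation 543 and 414. At a log2 fold change of at least 1 in size there were 407 and 305, so neither direction can be called the more frequent. The rising genes went from 2.78% to 10.4% of summed FPKM in wild type, from 6.48% to 25.1% in the knockout and from 2.12% to 10.7% in overexpression. The falling genes went from 20.3% to 6.16% in wild type, from 14.1% to 4.36% in the knockout and from 11.6% to 5.05% in overexpression. Most of the rise came by 72 h in wild type, where the median log2 change was 1.41 by 72 h and 1.44 by 96 h. In the knockout it was 0.79 and 1.25, and in overexpression 1.31 and 1.60.

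KFH43158.1 rose from 2.84 to 113 FPKM between 48 and 96 h in wild type, from 14.1 to 393 in the knockout and from 0.214 to 333 in overexpression. Its log2 fold change was 5.90 (SE 0.63, limma adjusted p = 0.00759). KFH43741.1 was listed at 0 in all 3 strains at 48 h and in the knockout at 72 h, and at 135, 137 and 87.5 FPKM at 96 h in wild type, knockout and overexpression. It passed the test (limma adjusted p = 0.0338), though it too is a gene with gaps at 0. Its values at 96 h in wild type and the knockout equal, in every digit given, those of other genes with gaps in the same library. These levels may thus rest on few reads. KFH40521.1 fell from 30.5 to 3.78 FPKM in wild type, from 69.7 to 1.59 in the knockout and from 263 to 2.20 in overexpression, a log2 fold change of -4.62 (SE 0.60, limma adjusted p = 0.0117). KFH42616.1 fell from 5511 to 459 FPKM, from 5687 to 49.2 and from 2714 to 267 in the same order, a log2 fold change of -4.58 (SE 0.74, limma adjusted p = 0.0165).

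The 1033 genes became 356, 413 and 328 without wild type at 48, 72 and 96 h, and 612 and 124 without the knockout at 72 and 96 h. Without overexpression at 48, 72 and 96 h they became 396, 428 and 93, and 62 genes were called whichever library was left out. KFH43741.1 lost its call without wild type at 48 or 96 h (adjusted p = 0.101 and 0.0675) and without the knockout at 96 h (0.111). It also lost it without overexpression at 48, 72 or 96 h (0.0960, 0.0604 and 0.110), and KFH42616.1 without overexpression at 96 h (0.0565).

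Strain and time differences were also set against each other in libraries they do not share. Across genes, knockout minus wild type at 48 h correlated at r = 0.174 with the change from 48 to 96 h in overexpression. Overexpression minus wild type at 48 h correlated at r = -0.0692 with the change in the knockout, with 43.4% of rising and 55.4% of falling genes higher in overexpression. The fitted knockout and 96 h effects correlated at r = 0.164 over all tested genes and at 0.0573 over the 7351 called for neither, a list without the genes that changed most, which cannot decide between explanations. Of the 1274 genes that rose at least 2-fold in overexpression, 70.1% were higher in the knockout than in wild type at 48 h, and of the 1366 that fell, 54.5%. Over all tested genes the median log2 difference from wild type at 48 h was 0.114 in the knockout and 0.116 in overexpression. Most genes were thus higher in each mutant at 48 h, and these shares have no baseline. Among the 148 genes rising from 48 to 72 h, 5 were called higher and 31 lower in overexpression than in wild type. Among the 508 rising from 48 to 96 h these numbers were 14 and 51. Falling genes were also lower more often, with 1 and 4 of the 62 falling by 72 h and 7 and 19 of the 525. Over all 8482 tested genes the numbers were 64 and 215, so lower calls outnumbered higher ones in every group. The 508 rising genes were called lower more often than all tested genes or the 525 falling genes. They were also called higher more often, and whether this bears on the time course was not tested.

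**Figure D4:**
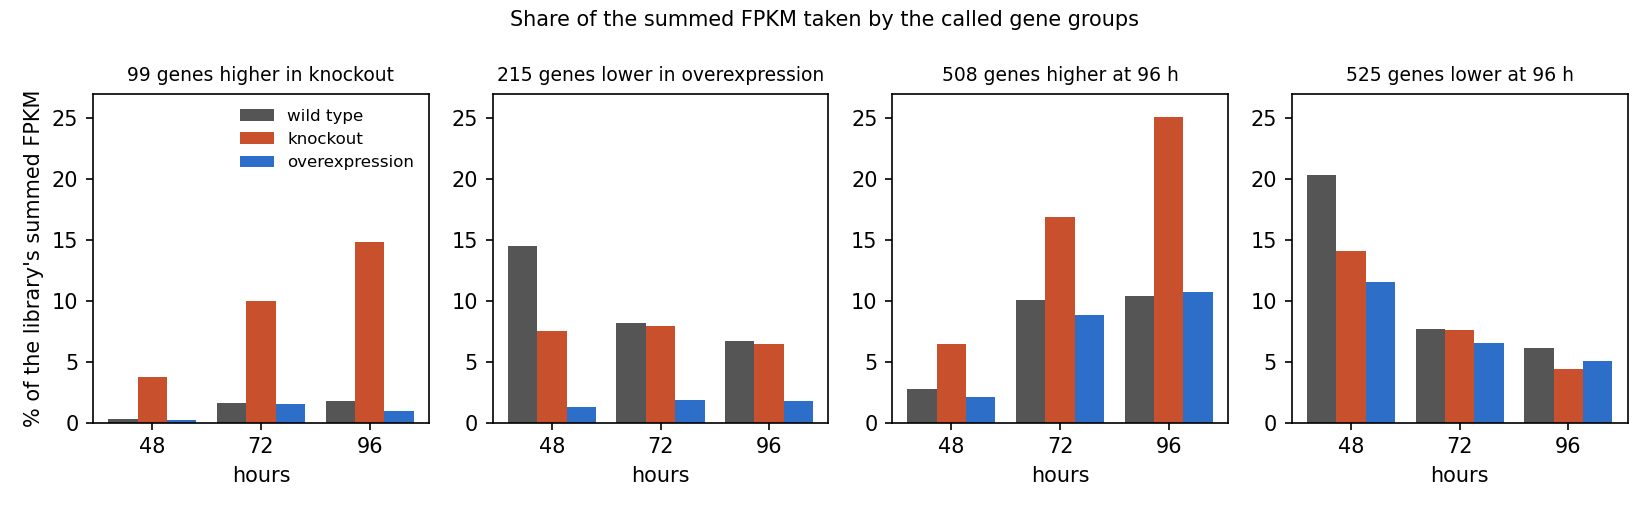
Percent of each library's summed FPKM taken by 4 groups of called genes, with 1 bar per library, coloured by strain and grouped by hours in culture. The 99 genes higher in the knockout reach 14.8% there at 96 h, and the 215 genes lower in overexpression stay at or below 1.88% in that strain.

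From 48 to 72 h, 148 genes rose and 62 fell, and 146 and 59 of these were also called between 48 and 96 h in the same direction. The count of 210 was 31, 0 and 44 without wild type at 48, 72 and 96 h. It was 320, 46 and 118 without the knockout at those times, and 68, 16 and 79 without overexpression, and 0 genes were called whichever library was left out. From 72 to 96 h limma called 1 gene, with 281 at an unadjusted p under 0.05, fewer than the 424 that chance gives. This gene, KFH41605.1, chosen after its values were seen, is listed at 0 in all 3 strains at 72 h.

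No gene passed the test for a different slope over time between the knockout and wild type, or between overexpression and wild type. limma gave 0 genes in each case, with lowest adjusted p of 0.144 and 0.0675. In simulated data these tests called only 6% and 10% of log2 slope differences of 1 per 24 h. The absence of calls therefore does not show that the time courses were alike. At an unadjusted p under 0.05 there were 467 and 792 genes, against 424 by chance. At single times, the knockout and wild type were at least 2-fold apart on the log2(FPKM + 1) scale for 1316, 1172 and 1270 genes at 48, 72 and 96 h. Overexpression and wild type were so for 1609, 1134 and 1425 genes, and none of these counts has a replicate check.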

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

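The tests on genes with gaps at 0, those on KFH48583.1, the check of falling genes in the knockout, the overlaps after rescaling, and the overexpression values at 72 h and from 72 to 96 h were chosen only after those values were seen. The tests of strain effects against the time course at 96 h, and the counts over other splits of the libraries, were set before their results were seen. For the time course the bounds set beforehand, 0.1 and -0.1, would have taken the knockout value as support and the overexpression value as evidence against a lag. They were replaced after the values were seen, as was the bound for genes switched off in a whole strain, which would have argued against it, and all 3 are left open.

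For 3 named genes a strain changed between 48 and 96 h in the opposite direction from wild type. KFH44385.1 fell by 0.78 on the log2 scale in overexpression and rose by 3.18 in wild type. KFH48583.1 rose by 0.62 in the knockout, where wild type changed by -1.03. KFH44846.1 rose by 0.41 in the knockout, where wild type changed by -0.28. Tests of the difference in slope did not pass for these genes, with limma adjusted p of 0.554, 0.871 and 0.938, and each strain and time has 1 library.

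Genes higher in the knockout were often genes that rose with time, with 52 of the 99 also called higher and 3 called lower at 96 h than at 48 h, and for the 80 lower genes 14 and 12. Scaling by a few abundant genes is argued against, since median-of-ratios rescaling gave 181 knockout calls against 179, and the 52 became 53, with 43 after quantile normalisation and 48 with equal FPKM totals. A candidate explanation is that knockout cultures were further along the time course, since across genes the knockout and 96 h effects correlated at r = 0.164 (Spearman 0.0665), where simulated unchanged strains gave -0.0804 to 0.0755. Of the 525 falling genes, 3 were called higher and 12 lower in the knockout, but their median log2 difference of 0.05 was that of all genes, 0.05, so this and a direct effect on late genes both stay open. Overexpression cultures lagging behind also stays open, since the values go both ways: the overexpression effect correlated at r = -0.0341 (Spearman 0.00196) with the 96 h effect (simulated -0.0884 to 0.0755), at -0.129 with the 72 h effect (simulated -0.0596 to 0.0646) and, opposite to a lag, at 0.156 with the change from 72 to 96 h (simulated -0.0733 to 0.0690).

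Of 83 genes with gaps at 0, 55 were tested. Calls among them numbered 0 for knockout against wild type, 1 for overexpression against wild type, 3 for overexpression against knockout, 2 for 72 against 48 h, 2 for 96 against 48 h and 1 for 96 against 72 h. Few reads on very short genes may be the source of the gaps, since 26.5% of their detected values equal another gene's value in the same library to 6 digits, against 1.1% for other genes at 10 FPKM or more in all libraries and 3.59% for values of other genes under 1 FPKM. Genes switched off in a whole strain stay open, as 43 of the 83 were at 0 in all 3 libraries of at least 1 strain, but only 5 of these had another strain without zeros. In 1 of the 5 no strain was mixed: KFH49082.1, chosen after its values were seen, is listed at 0 in all 6 wild-type and knockout libraries and at 24.8, 29.8 and 18.9 FPKM in overexpression at 48, 72 and 96 h.

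KFH48583.1 is the 1 gene detected in wild type whose highest knockout level is at most 0.5 of its lowest wild-type level and whose lowest overexpression level is at least 4 times its highest wild-type level. This is the profile the manipulated locus might have, but 1 gene with a profile cannot tie an identifier to AcmybA, and no name or sequence was used here. Removal of the whole counted length is argued against by its lowest knockout level of 3.36 FPKM. A locus with part of its length left, and a gene downstream of AcmybA, cannot be told apart.

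The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real split gave 179 genes for knockout against wild type and the highest other split 1. For overexpression against wild type these were 279 and 0, and for overexpression against knockout 756 and 1. For 72 against 48 h they were 210 and 1, and for 96 against 48 h 1033 and 2. In each of these 5 the real split was the only 1 of 10 with as many genes. For 96 against 72 h, 3 splits gave 1 gene or more and the highest other gave 2. For both slope comparisons all 10 splits gave 0 genes or more, and the highest other gave 2. Of the 10 splits, 4 part all 3 pairs of libraries that share a time, or a strain in the comparisons of times. Among these the highest other count was 1, 0 and 1 for the strain comparisons in the order above, 0, 2 and 0 for the time comparisons, and 0 for both slopes.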

How the results depend on the processing

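The 2 alternatives that drop genes at 0 were chosen after seeing the data, and the others before. Named genes gave 368 pairs of gene and alternative, of which 321 kept direction and threshold, 47 lost the threshold and 0 reversed. Alternatives in the trend, the filter or the time term leave the fold change of a named gene as it was, so they cannot reverse it. Adding a 2-fold threshold leaves its p-value as it was too. Part of these numbers was thus fixed in advance. Leaving out 1 library gave 30 to 235 genes for knockout against wild type, 14 to 264 for overexpression against wild type and 302 to 765 for overexpression against knockout. It gave 0 to 320 for 72 against 48 h, 93 to 995 for 96 against 48 h and 0 to 1 for 96 against 72 h. Slopes gave 0 to 2 (knockout) and 0 to 1 (overexpression), and oppositely moving genes 0 to 27. Where 1 library was left out, its strain is assumed to vary like the others, and the loss of power was not gauged. Without 48 h, knockout against wild type gave 104 genes, overexpression against wild type 210, overexpression against knockout 865 and opposite genes 8. Without 72 h it gave 16, overexpression against wild type 3, overexpression against knockout 167 and opposite genes 0. Without 96 h these were 12, 16, 236 and 0, and why was not tested. With no time term (no replicate block) they were 20, 67, 286 and 2, the time differences then counting as spread. The cause of the following shifts was not tested. The 6 libraries of both strains alone gave 181 for overexpression against wild type and 416 against knockout. Linear time gave 115 for knockout against wild type and 3 opposite genes. Equal FPKM totals gave 175 for overexpression against wild type and 7 opposite genes, and moved the median of all genes by 0.11 (log2) in overexpression against knockout. Without the intensity trend, 72 against 48 h gave 103 and opposite genes 6. Quantile normalisation gave 1 overexpression slope. Opposite genes numbered 53 at an unadjusted p under 0.01 and 125, 123 and 163 by fold at 48, 72 and 96 h alone. Dropping genes with gaps at 0, or any gene at 0, left 0 genes for 96 against 72 h, and the latter gave 1 overexpression slope. The count tests and gene-list alternatives were not run, for want of counts and matched genes. Labels give no replicate numbers. Strains share times, and time is the block in the strain plus time fit. Deeper overexpression libraries limit what low genes can show.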

Other observations

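Some abundant transcripts differed between strains, while KFH42067.1 was the highest of both wild type and the knockout at 48 h. KFH43806.1, chosen after its values were seen, was at 7683, 25697 and 32888 FPKM in the knockout at 48, 72 and 96 h. In wild type it was at 237, 3642 and 3439 FPKM, and in overexpression at 181, 2752 and 1337. KFH41895.1, chosen in the same way, was at 2273, 7391 and 23317 FPKM in the knockout, against 31.7, 1899 and 1405 in wild type and 29.6, 1658 and 705 in overexpression. KFH41657.1, also chosen after its values were seen, was at 40692 FPKM in overexpression at 48 h, against 14611 in wild type and 15127 in the knockout, and at 3352, 6823 and 8363 FPKM in the same order at 96 h.

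Overexpression libraries changed most between 48 and 96 h, with 2640 genes at least 2-fold apart, against 1668 in wild type and 1557 in the knockout. These counts compare single libraries and have no test.

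Whether called genes sit beside each other was tested as a hypothesis, taking the order of identifiers as a stand-in for genome order, which was not checked. For overexpression against knockout, 52 pairs of adjacent identifiers were called in the same direction. The mean of 1000 shuffles was 33.8, their 95th percentile 43 and their highest 52, so the observed number was in excess but did not exceed every shuffle. At 2 identifiers apart there were 50 pairs, also past a 95th percentile of 43. For 96 against 48 h there were 76 adjacent pairs, against a 95th percentile of 71. For knockout against wild type there was 1 such pair against a mean of 1.77, and for overexpression against wild type 8 against 5.62, both within the shuffles. The knockout had 5 pairs at 3 apart (95th percentile 4) and overexpression 11 at 2 apart (95th percentile 10). The knockout at 2 apart had 4 pairs, above the mean of 1.84 but not past the 95th percentile of 4. No excess was seen for overexpression at 3 apart (2, mean 5.54) or 96 against 48 h at 3 apart (61, mean 60.1). The bound set beforehand asked every strain comparison to pass and would have argued against grouping. It was replaced after the values were seen, since lists of 179 and 279 genes with so few expected pairs are too short to decide. Grouping of neighbours is left open. Checks for reads running into the next gene and for near-identical copies were planned with this test and dropped after their values were seen, so neither was weighed and both stay open. Their values were 47 pairs at 3 identifiers apart, against a 95th percentile of 43, and 84.6% of the 52 adjacent pairs with a log2 ratio varying by an SD of at least 0.5 over the libraries.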
